A study of Homo sapiens with 6 samples.

How the data were processed

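Expression was measured in 6 cultures of the DAOY medulloblastoma line, 3 with a non-targeting hairpin (shNT) and 3 with a hairpin against PTX3 (shPTX3). Per the labels, total RNA was extracted with TRIzol, 100 ng was labelled with the GeneChip WT PLUS kit, and each sample was hybridised to a Clariom D human array. The array has probes for coding and non-coding transcripts, grouped into transcript clusters. The authors deposited 1 log2 value per transcript cluster and array. The submitters' processing notes name RMA and Affymetrix Expression Console, with no versions. RMA corrects the background, equalises the distributions of the arrays and summarises the probes of a cluster, so a change shared by most transcripts would not be seen, and differences of dim clusters are compressed. Clusters are annotated to the human genome build hg38, per the file headers. A second deposited table held the same log2 values (largest difference 0 over 135750 clusters) and a detection flag per cluster and array, whose rule is not given in the sources used here. Its overall F-test column held the value 1 for each of the 135750 clusters, so it carried no usable comparison of the authors' own. Values are rounded to 2 decimals.

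Group and replicate number were taken from the sample descriptions. The title of 1 shPTX3 sample gives another replicate number than its description, and the description was used. The labels call the replicates biological. Of the 135750 clusters, 80168 carried exactly 1 gene symbol, 5993 several and 49589 none. Clusters with several symbols or none were left out of the main comparison. For each symbol the cluster with the highest mean over the 6 arrays was kept, which gave 75813 genes. A current NCBI RefSeq symbol was already given for 31384 of them, 1262 were updated through an accession and 565 through a synonym, and 42602 kept the name of the deposited table. RefSeq lists 18170 of the tested genes as protein-coding, and 56 further protein-coding genes were measured by clusters with several symbols alone. Coordinates are those of the deposited table.

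Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior, no covariate, shPTX3 minus shNT, two-sided), with Benjamini-Hochberg adjustment over the 75813 genes and a threshold of 0.05 on the adjusted p. Adjusted p-values of genes below are limma's. The exact permutation test of 3 against 3 arrays cannot give a p below 0.1. Gene lists were tested with limma's camera at a preset correlation of 0.01 between members and adjusted over the 42 lists. Each list was also tested with an estimated correlation and with fry, and its median was ranked among 10000 random lists matched on size and mean signal. The lists were written from textbook knowledge before the data were examined. They cover hedgehog, FGF and ERK feedback, the FGF system, pentraxins and complement, NF-kB and cytokines, type I interferon, antigen presentation, G1/S, G2/M, mesenchymal and epithelial genes, collagens, integrins, matrix proteases, TGF-beta, YAP, WNT, NOTCH, neural stem and neuronal genes, p53, apoptosis, the unfolded protein response with ATF4, hypoxia, cholesterol, fatty acids, oxidative phosphorylation, NRF2, autophagy, ribosomal proteins, axon guidance, angiogenic factors, histones, small nucleolar RNAs and microRNA precursors. Markers of 7 other cell types (fibroblast, endothelial, leukocyte, epithelial, astrocyte, oligodendrocyte and neuron) were among them.

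The rule for the genes named was also fixed before the data were examined. It took PTX3, the genes past the threshold or, since none passed, the 5 protein-coding genes with the smallest p in each direction whose groups did not overlap, the 3 non-coding genes with the largest difference in each direction, and the 4 members with the smallest p of each called list and of the hedgehog, FGF, cell cycle, mesenchymal, NF-kB and interferon lists. Protein-coding was read as RefSeq gives it, and names of predicted transcripts were counted as uncharacterised. Of the non-coding genes that the rule takes, 1 is not reported here.

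Data were simulated over the 75813 genes with noise of each gene's own spread and 50 changed genes of each size, all above the median signal. The limma fit called 6% of 2-fold, 62% of 4-fold, 84% of 8-fold and 94% of 16-fold changes, with 2 false calls. The adjustment depends on how many genes change at once, so these shares do not hold where few genes change. A list moved by −0.3 on the log2 scale was called by camera in 17 of 20 simulated runs with independent members, with 1 false call among 760 lists. In the 5 lists called below, the estimated correlation between members ranged from 0.098 to 0.708. The simulated rate of false calls therefore does not apply to them. The number of arrays limits the precision of each value. Alternatives fixed before the data were examined were other eBayes priors, a signal filter, the mean of all clusters of a gene, every cluster, quantile normalisation or median centring of the deposited values, the replicate number as a block, a plain two-sample test, other thresholds, treat against a fold of 1.2, other list tests, and leaving out each array. Chosen after seeing the data were replicate 1 as a batch term (alone, with protein-coding genes, with detected protein-coding genes and a robust signal-dependent prior, and without shNT replicate 2), replicates 2 and 3 alone, protein-coding genes alone, genes detected on at least 3 arrays, naming clusters of several symbols by their RefSeq symbol, and an estimated correlation in each other fit of the lists. Plots were drawn with matplotlib 3.10.9.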

Results

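Gene expression was profiled in DAOY cells, an established human line that the labels place in the sonic hedgehog (SHH) subgroup of medulloblastoma. The cells carried a short hairpin RNA against PTX3 or a non-targeting hairpin, and the comparison asked which transcripts differ when PTX3 is silenced. PTX3 encodes pentraxin 3, a secreted pattern recognition protein that binds complement components and FGF2. Each group had 3 biological replicates, each on its own array. Median log2 signals lay between 5.25 and 5.35 on the 6 arrays. The authors' software counted 63.0% and 64.2% of the transcript clusters as detected on the replicate 1 arrays of shNT and shPTX3, and between 68.2% and 71.7% on the other 4 arrays. No pair of arrays held the same value for more than 1.07% of the 75813 tested genes.

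PTX3 itself was examined first. Its transcript cluster (TC0300009301.hg.1, chromosome 3, 157436789 to 157443628, plus strand, hg38) is annotated to this gene. PTX3 signal was 9.48 ± 0.45 in shNT and 7.37 ± 0.47 in shPTX3 cells (log2, mean ± SD, n = 3 each). The shNT arrays read 9.40, 9.96 and 9.08, and the shPTX3 arrays 7.89, 7.25 and 6.97, so that the groups did not overlap. The log2 difference was −2.11 (SE 0.32, 95% CI −2.82 to −1.40), a signal 4.32-fold lower (2.64 to 7.06), with 23.2% of the shNT level remaining. PTX3 was detected on all 6 arrays. It ranked 1 of 75813 genes by limma's p (7.34e-05 before adjustment), but its adjusted p was 0.999. Its rank was 2 with replicate 1 as a batch term and 4 with replicates 2 and 3 alone. The exact permutation test gave a two-sided p of 0.1, the smallest that 3 against 3 arrays allow.

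Next, genes other than PTX3 were compared between shPTX3 and shNT cells. Among genes with lower signal, IGFBP3, a binding protein of insulin-like growth factors, read 13.91 ± 0.41 in shNT and 12.56 ± 0.58 in shPTX3 cells (log2, mean ± SD, n = 3), a difference of −1.35 (SE 0.33). TGM2, the transglutaminase that cross-links matrix proteins, differed by −1.09 (SE 0.28), and SLC25A31, a mitochondrial ADP/ATP carrier, by −0.95 (SE 0.22). The imprinted DLK1 and the ERK pathway inhibitor SPRED3 were lower by smaller amounts, with differences of −0.85 (SE 0.21) and −0.79 (SE 0.21). On the higher side stood PIERCE1 at 1.07 (SE 0.30), the ERBB4 ligand NRG4 at 1.04 (SE 0.28), the kinase gene ALPK2 at 0.92 (SE 0.26), the secreted OLFML3 at 0.86 (SE 0.25) and the rhomboid family member RHBDL3 at 0.78 (SE 0.22), or 0.41 as the mean of all its clusters. The rule took these 10 genes only where the 3 shPTX3 arrays lay on one side of the 3 shNT arrays, and in none did the difference pass the threshold (limma adjusted p = 0.999 each). SLC25A31 lay near the detection limit, with 2 shNT and 0 shPTX3 arrays counted as detected.

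**Figure D1:**
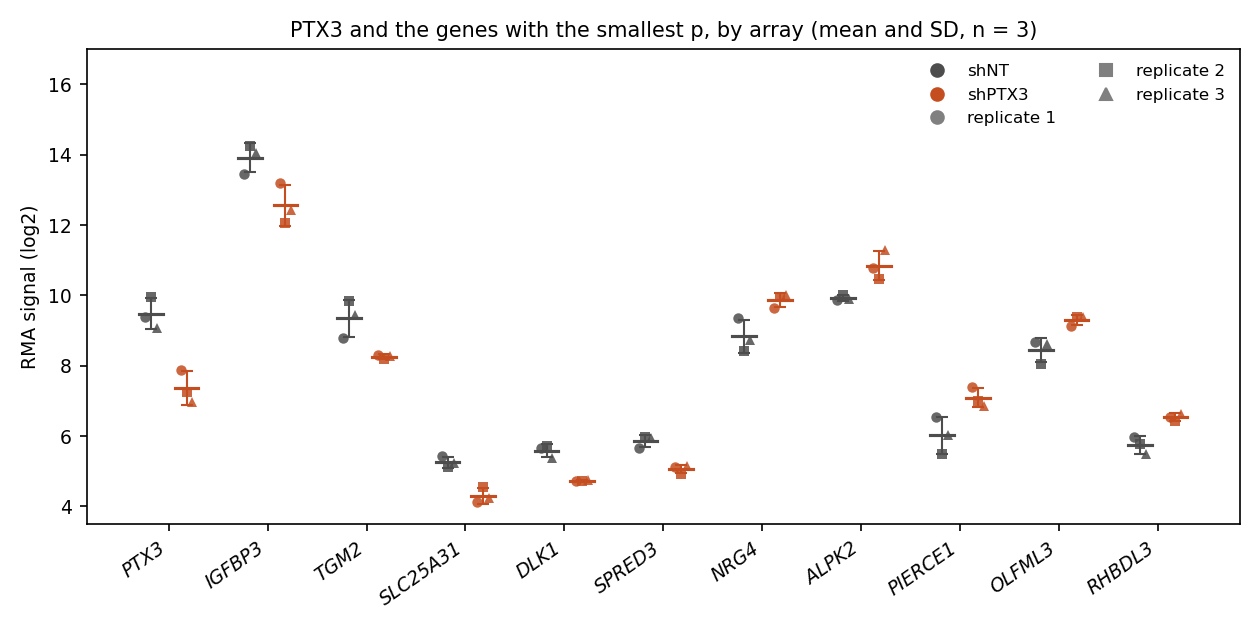
Log2 RMA signal (vertical axis) of PTX3, 5 genes lower and 5 genes higher in shPTX3 cells (horizontal axis), with 1 point per array, horizontal lines for group means and error bars for the SD (n = 3). PTX3 lay between 9.08 and 9.96 on the shNT arrays and between 6.97 and 7.89 on the shPTX3 arrays. The other 10 genes were taken among those whose groups do not overlap, and no gene passed the adjusted threshold.

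Over all 75813 genes, limma called 0 at an adjusted p under 0.05, hence 0 higher, 0 lower and 0 changed at least 2-fold. At an unadjusted p under 0.05 there were 2632 genes, 1143 higher and 1489 lower, where chance alone gives 3791. A plain two-sample test on the same values also called 0 genes. Groups did not overlap for 5832 genes (7.69%), against 10% by chance. Of these, 81 were at least 2-fold higher and 114 at least 2-fold lower in shPTX3 cells. Among the non-coding genes with the largest differences were MIR5584 (1.13) and MIR548AP (1.05) on the higher side, and MIR301A (−1.29), SNORA38B (−1.16) and LOC101929762 (−1.08) on the lower side, each with an adjusted p of 0.999. The precursors MIR5584 and MIR301A were detected on 0 of the 6 arrays, and LOC101929762 on 1 shNT and 0 shPTX3 arrays. Without shNT replicate 2, SNORA38B differed by −0.43, and without shNT replicate 3, LOC101929762 by −0.70. Of the 60 genes that the naming rule takes, 25 had a difference smaller by more than 1.5 times without shNT replicate 2, between 4 and 7 without each other array, and 38 without at least 1 of the 6 arrays.

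Gene lists were then compared, and 5 of the 42 lists passed camera's threshold with the preset correlation, 2 lower and 3 higher in shPTX3 cells, while 0 passed with an estimated correlation between members or by fry. Targets of FGF and ERK signalling that feed back on the pathway shifted down (21 of 26 measured members lower, median log2 difference −0.30, camera adjusted p = 0.00384 with the preset and 0.885 with an estimated correlation, 0.903 by fry). Members with the smallest p were SPRED3 (−0.79), the phosphatase DUSP4 (−0.58), the FGF receptor antagonist IL17RD (−0.80) and SPRED1 (−0.45). NF-kB targets and inflammatory cytokines also shifted down (31 of 35 lower, median −0.25, camera adjusted p = 0.00139 with the preset and 0.885 with an estimated correlation, 0.903 by fry), among them the chemokines CXCL8 (−1.14, SE 0.36) and CXCL2 (−0.48), the granulocyte growth factor CSF3 (−0.60) and the alarmin IL33 (−0.59). CSF3 was counted as detected on 1 shNT and 0 shPTX3 arrays, so its difference is uncertain. Without shNT replicate 2, IL17RD differed by −0.42, SPRED1 by −0.28, CSF3 by −0.40, IL33 by −0.365 and CXCL2 by −0.295. In both lists 0 members passed over all genes and 0 when adjusted over the list alone.

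Oxidative phosphorylation genes shifted up (36 of 38 higher, median 0.14, camera adjusted p = 0.0015 with the preset and 0.885 with an estimated correlation, 0.903 by fry), among them the complex I subunits NDUFA2 (0.46) and NDUFB3 (0.34), the ATP synthase subunit ATP5MC1 (0.39) and the cytochrome oxidase subunit COX5A (0.36). Cholesterol synthesis and uptake genes shifted up as well (19 of 24 higher, median 0.24, camera adjusted p = 0.00464 with the preset and 0.885 with an estimated correlation, 0.903 by fry). They included squalene synthase FDFT1 (0.45), squalene epoxidase SQLE (0.51), HSD17B7 (0.49) and ACAT2 (0.37). Replication-dependent histones were the other list that shifted up (36 of 43 higher, median 0.15, camera adjusted p = 0.00893 with the preset and 0.885 with an estimated correlation, 0.903 by fry), with H3C6 at 0.52, H4C3 at 0.63, H2BC3 at 0.39 and H2AC8 at 0.54. Without shNT replicate 2, NDUFB3 and COX5A differed by 0.175 and 0.19, FDFT1, HSD17B7 and ACAT2 by 0.26, 0.315 and 0.18, and H4C3, H2AC8 and H2BC3 by 0.06, 0.05 and 0.23. ATP5MC1 differed by 0.24 without shNT replicate 1, and SQLE by 0.28 without shPTX3 replicate 1. In these 3 lists 0 members passed over all genes or adjusted over the list alone. Among random lists matched on size and signal, which leave out the correlation between members, the 5 medians stood at percentile 0 (FGF and NF-kB), 99.99 (histones) and 100 (oxidative phosphorylation and cholesterol). Some lists that did not pass lay as far out: interferon and small nucleolar RNAs at 0, and NRF2 and glutathione at 100. Others lay nearly so: angiogenic factors at 0.05, epithelial genes at 0.12 and G1/S at 99.9.

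Averaged per array, the FGF and ERK feedback list lay at 0.14 ± 0.02 in shNT and −0.14 ± 0.24 in shPTX3 cells, relative to each gene's mean (SD, n = 3, exact permutation p = 0.1). Oxidative phosphorylation lay at −0.08 ± 0.11 and 0.08 ± 0.04 (SD, n = 3, exact permutation p = 0.1). In these 2 lists alone among the 42 the groups did not overlap, where chance alone gives 4.2 of independent lists, and the groups lay apart by only 0.03 and 0.002. No list can go below 0.1 by this test. The NF-kB list lay at 0.15 ± 0.51 and −0.15 ± 0.27 (SD, n = 3, exact permutation p = 0.5), cholesterol at −0.10 ± 0.22 and 0.10 ± 0.21 (SD, n = 3, exact permutation p = 0.3), and histones at −0.08 ± 0.38 and 0.08 ± 0.29 (SD, n = 3, exact permutation p = 0.7). Between the replicate 1 arrays of both groups, the median difference was 0.01 for FGF and ERK feedback and 0.08 for NF-kB, against −0.34 and −0.48 between the others. For oxidative phosphorylation, cholesterol and histones it was 0.20, 0.16 and 0.19 between the replicate 1 arrays and 0.13, 0.28 and 0.12 between the others. Without shNT replicate 2, none of the 42 lists passed: the medians were −0.23 for FGF and ERK feedback (adjusted p = 0.0817), −0.06 for NF-kB (0.60), 0.12 for oxidative phosphorylation (0.129), 0.15 for cholesterol (0.214) and −0.03 for histones (0.775). Without shNT replicate 3 the FGF (median −0.24) and cholesterol lists (0.19), without shPTX3 replicate 1 the cholesterol (0.13) and histone lists (−0.002), and without shPTX3 replicate 2 the FGF list (−0.15) did not pass. Without shNT replicate 1 the medians were larger for NF-kB (−0.515), cholesterol (0.41) and histones (0.30), as they were for histones without shPTX3 replicate 3 (0.26). With replicates 2 and 3 alone, oxidative phosphorylation (0.125) and histones (0.12) did not pass.

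**Figure D2:**
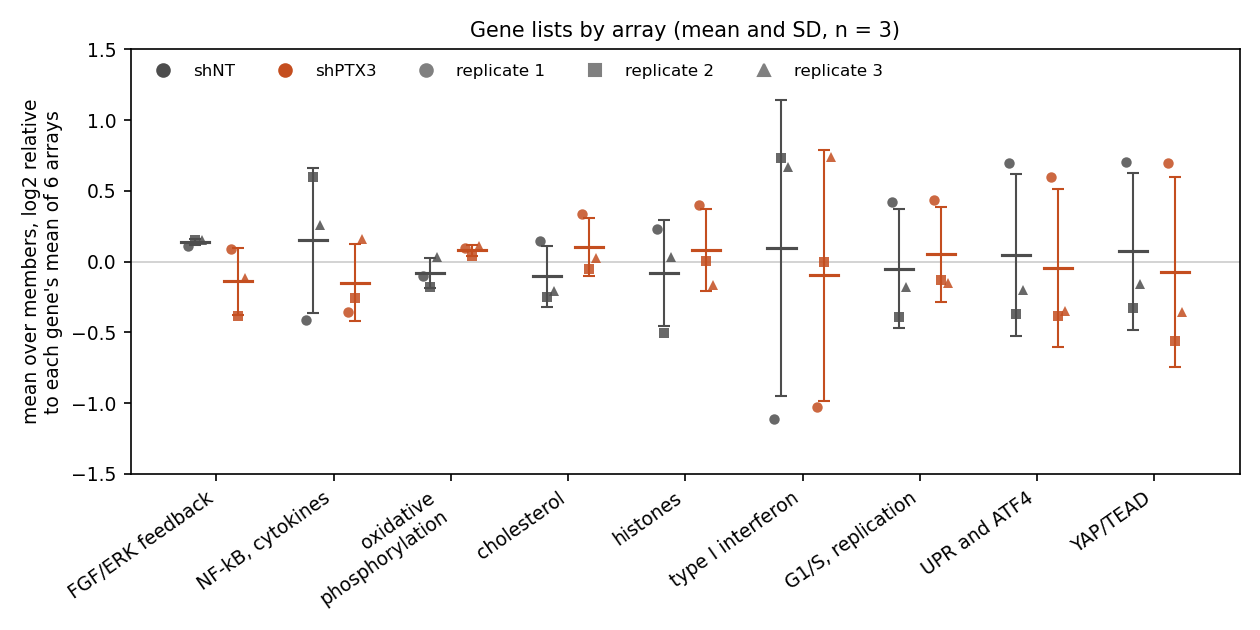
Mean log2 signal of the members of 9 gene lists on each array, relative to each gene's mean over the 6 arrays (vertical axis), with 1 point per array, horizontal lines for group means and error bars for the SD (n = 3). Groups do not overlap in the FGF/ERK feedback and oxidative phosphorylation lists, by a distance of 0.03 and 0.002, while the interferon list lies at −1.11 and −1.03 on the replicate 1 arrays and between 0.00075 and 0.74 on the others.

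Lists close to the biology of the line and of PTX3 did not pass in the comparison of all 6 arrays. Hedgehog pathway genes had a median of −0.06 (15 of 26 lower, camera adjusted p = 0.759). Within the list, SFRP1 differed by −0.53, CCND2 by −0.36, the receptor SMO by −0.23 and its inhibitor PTCH1 by 0.27. FGF ligands, receptors and modulators had a median of −0.04 (18 of 32 lower, adjusted p = 0.759), with FGF2 at −0.76 (SE 0.34), KLB at −0.30 (detected on 2 shNT and 0 shPTX3 arrays), FGFR4 at −0.28 and SDC2 at 0.27. Cell cycle genes were mostly higher without passing, 32 of 40 in the G1/S list (median 0.11, adjusted p = 0.176) and 33 of 45 in the G2/M list (median 0.09, adjusted p = 0.201). Examples were CDT1 (0.43), TK1 (0.40), E2F2 (0.34), HMMR (0.52), CDC25C (0.37) and KIF20A (0.40), with UNG (−0.40) and CENPA (−0.25) on the other side. Mesenchymal genes had a median of 0.07 (16 of 28 higher, adjusted p = 0.525), with the transcription factors SNAI1 (0.70) and SNAI2 (0.48) and S100A4 (0.52) higher and the cadherin CDH11 (−0.77) lower. Type I interferon genes had a median of −0.17 (30 of 40 lower, adjusted p = 0.336), with EPSTI1 and MX1 at −0.45 each, MX2 at −0.51 and OAS3 at 0.22. With replicate 1 as a batch term the interferon and G1/S lists passed (camera adjusted p = 0.0276 and 0.0448), and so did interferon with replicates 2 and 3 alone (0.00113). Among replicates 2 and 3, the interferon mean was lower on shPTX3 replicate 2 alone (0.00075). It was 0.736 on shPTX3 replicate 3 and 0.733 and 0.667 on the shNT arrays. With an estimated correlation neither list passed in the same fits (adjusted p = 0.871 for both with the batch term, 0.984 for interferon with replicates 2 and 3 alone). Leaving out 1 array moved these lists both ways. Without shNT replicate 1 the medians were −0.66 for interferon, 0.32 for G1/S and 0.20 for G2/M, and all 3 passed with the preset correlation. Interferon also passed without shPTX3 replicate 3 (−0.52), G1/S without shPTX3 replicate 2 or 3 (0.19 and 0.22) and G2/M without shPTX3 replicate 2 (0.14), and none of the 42 lists passed in these fits with an estimated correlation. The medians had the opposite sign without shPTX3 replicate 1 (0.14, −0.06 and −0.005) and without shNT replicate 2 (0.09, −0.04 and −0.003), and the interferon median also without shNT replicate 3 (0.06). Without shNT replicate 2 but with replicate 1 as a batch term, the 3 medians kept their sign (−0.11, 0.04 and 0.04). No member of these lists passed over all genes, and the count adjusted over the list alone was 0 in each.

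The difference shrank in many of these members when 1 array was left out. Leaving out 1 array also changes the weight of replicate 1 in its group. Part of the shrinkage can therefore follow from the replicate 1 difference described below. With replicate 1 as a batch term and without shNT replicate 2, CDT1, TK1, MX1 and OAS3 differed by 0.25, 0.24, −0.23 and 0.09. Without shNT replicate 2, the cell cycle genes CDT1, TK1, E2F2, HMMR, CDC25C and KIF20A differed by 0.19, 0.15, 0.16, 0.29, 0.18 and 0.06, the interferon genes EPSTI1, MX1, MX2 and OAS3 by −0.18, −0.14, −0.335 and 0.10, and FGFR4 by −0.16. MX2 was at its smallest without shNT replicate 3 (−0.205), and UNG differed by −0.255 there. Without shPTX3 replicate 1, SMO differed by −0.08 and CDH11 by −0.445. Without shPTX3 replicate 2, FGF2 differed by −0.395 and CENPA by −0.09. Without shPTX3 replicate 3, PTCH1 differed by 0.05, S100A4 by 0.26 and SNAI2 by 0.305. Without shNT replicate 1, CCND2 differed by −0.18 and KLB by −0.195.

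Of the 31 lists left, none passed in the comparison of all 6 arrays, and 0 members passed over all genes or adjusted over the list alone. Median differences on the metabolic and stress side were 0.16 for NRF2 and glutathione (adjusted p = 0.0757), 0.13 for fatty acid synthesis, 0.08 for autophagy and lysosome, 0.05 for ribosomal proteins, 0.06 for hypoxia and glycolysis, 0.07 for p53 targets, −0.08 for apoptosis regulators and −0.08 for the unfolded protein response and ATF4. Among matrix and adhesion lists they were −0.20 for epithelial genes, −0.02 for collagens, 0.06 for integrins, −0.003 for matrix proteases and −0.11 for pentraxins and complement. Signalling lists had medians of 0.01 for TGF-beta, −0.08 for YAP, −0.03 for WNT and −0.06 for NOTCH. Angiogenic factors lay at −0.18, axon guidance at −0.05, neural stem genes at −0.01, neuronal genes at −0.05 and antigen presentation at 0.02. Small nucleolar RNAs lay at −0.08 and microRNA precursors at −0.03. Medians of the marker lists were −0.08 for fibroblasts, 0.12 for endothelial cells, −0.04 for leukocytes, −0.20 for epithelial cells, −0.08 for astrocytes, −0.01 for oligodendrocytes and −0.15 for neurons, with the smallest adjusted p at 0.308. The median and camera's direction had opposite signs for the TGF-beta, neural stem, neuronal, WNT and leukocyte lists, and the median and the mean (−0.01) for the integrins. Some of the 31 passed in other settings with the preset correlation, and none with an estimated correlation in any of 18 fits (adjusted p = 0.885 for NRF2 and glutathione over all 6 arrays). The NRF2 and glutathione list did so among genes above the median mean signal, with the mean of all clusters of a gene, among genes detected on at least 3 arrays, with the replicate number as a block, with replicate 1 as a batch term, and without shNT replicate 1, shPTX3 replicate 2 or shPTX3 replicate 3. Fatty acid synthesis passed without shNT replicate 1 or shPTX3 replicate 2. Epithelial genes passed with replicates 2 and 3 alone, among protein-coding genes with the batch term and, together with the YAP, unfolded protein response and small nucleolar RNA lists, without shPTX3 replicate 1. Angiogenic factors passed in 1 setting, detected protein-coding genes with the batch term and a robust signal-dependent prior. Epithelial genes and the NRF2 and glutathione list also passed there, and the latter also among protein-coding genes with the batch term.

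The widest separation among the arrays did not follow the hairpin. The replicate 1 arrays of both groups stood apart on the first principal component (33.4% of the variance), at 74.6 for shNT and 74.7 for shPTX3, with the other 4 arrays between −78.1 and −18.1. shNT replicate 2 stood apart on the second component (22.0%), at 79.7 against at most 22.2 for the others. Interferon response genes were lower on the replicate 1 arrays than on the other 2 of their group, by a median of −1.43 in shNT and −1.05 in shPTX3 cells, and in 28 of 40 members both replicate 1 arrays were the lowest (6.67% by chance). G1/S genes were higher, by 0.63 and 0.51 (both replicate 1 arrays highest in 34 of 40), as were YAP and TEAD targets, by 0.79 and 0.88 (17 of 20), and the unfolded protein response and ATF4 targets, by 0.72 in both groups (25 of 36). The NF-kB list was lower there, by −0.65 and −0.21, and the cholesterol list higher, by 0.49 and 0.39, as were the histones, by 0.41 and 0.45. These genes were chosen after their values were seen: the interferon-induced IFIT2 read 5.97 and 6.24 on the replicate 1 arrays and between 10.73 and 13.06 on the others, and OASL 7.31 and 7.18 against 11.85 to 13.84. The ATF4 target CHAC1 read 11.75 and 11.34 against 6.50 to 7.97, and BMP4 12.58 and 12.86 against 8.49 to 9.04. With replicate 1 as a batch term, limma again called 0 genes (3557 at an unadjusted p under 0.05), and camera called 8 lists with the preset correlation (the 5 above, interferon, G1/S, and NRF2 and glutathione) and 0 with an estimated correlation.

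**Figure D3:**
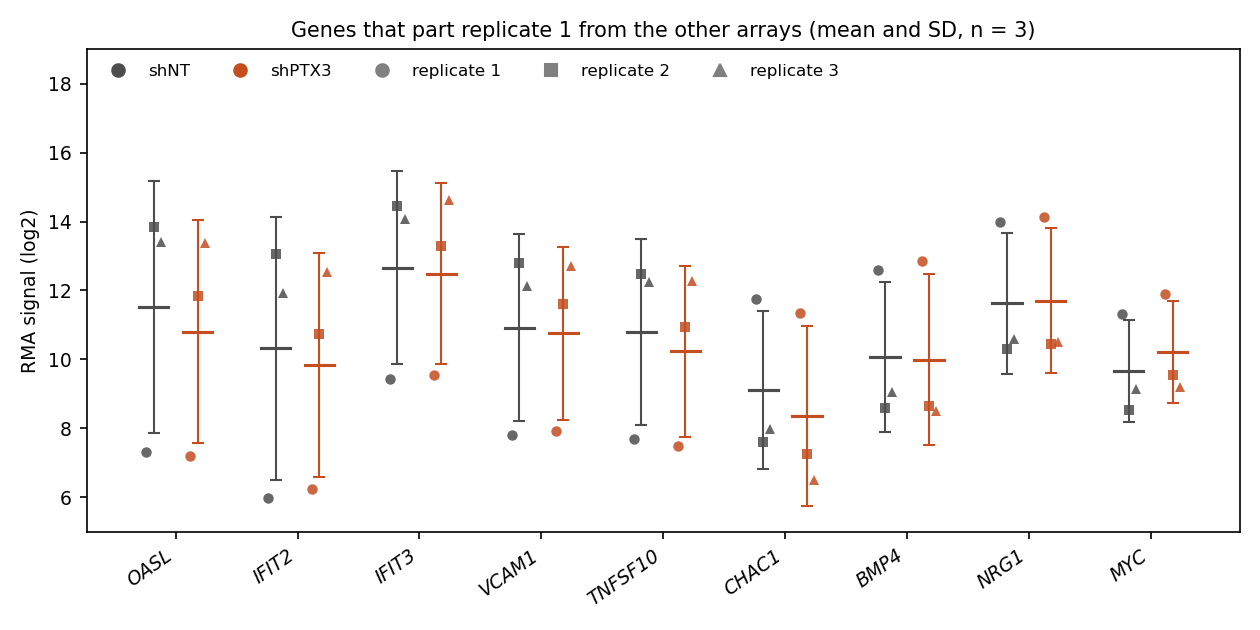
Log2 RMA signal (vertical axis) of 9 genes that part the replicate 1 arrays (circles) from replicates 2 and 3 (horizontal axis: gene), with horizontal lines for group means and error bars for the SD (n = 3). IFIT2 reads 5.97 and 6.24 on the replicate 1 arrays and at least 10.73 on the others, in both groups alike.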

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

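Every gene count, PTX3 and the named genes kept their direction and side of the threshold under all settings fixed before the data were examined: limma called 0 genes in each, and PTX3 lay between −2.37 and −1.87 (adjusted p between 0.95 and 1). The 59 other named genes kept theirs under the added settings too, wherever a setting held the gene. Their side of the threshold was nearly fixed in advance, since each had a limma adjusted p of 0.999 over all 6 arrays. They were also picked on these same arrays, so a kept direction is weak support. In size, 38 of the 60 genes under the naming rule shrank by more than 1.5 times without at least 1 array. Filters on signal, detection or protein-coding genes leave some named genes out, so those settings say nothing of them. Settings with replicate 1 as a batch term, replicates 2 and 3 alone, protein-coding or detected genes and clusters of several symbols were chosen after seeing the data. PTX3 passed in 1 of them, detected protein-coding genes with the batch term and a robust signal-dependent prior (−2.11, adjusted p = 0.0173), where it was the 1 gene called, 1 lower and 1 at least 2-fold, beside 10 lists; the cause was not tested. The count of 5 lists became 0 with an estimated correlation, in each of 18 fits of the lists, all but 1 chosen after seeing the data, 0 with fry, 8 with the batch term, 9 with the batch term over protein-coding genes, and 2 (FGF and ERK feedback, cholesterol) with the batch term and shNT replicate 2 left out. Leaving out 1 array gave 0 (shNT replicate 2) to 10 lists (shNT replicate 1), 3 without shNT replicate 3, 7 without shPTX3 replicate 1 and 8 without shPTX3 replicate 2 or 3. List medians that changed sign when 1 array was left out ranged from −0.0283 to 0.30 (histones), −0.12 to 0.0625 (hedgehog), −0.0675 to 0.0583 (FGF ligands and receptors), −0.0633 to 0.32 (G1/S), −0.005 to 0.20 (G2/M), −0.0217 to 0.10 (mesenchymal) and −0.66 to 0.14 (interferon). Also of opposite sign, with either correlation, were FGF ligands and receptors (0.0075), G1/S (−0.0442), G2/M (−0.00333) and interferon (0.085) without shNT replicate 2, interferon (0.0617) without shNT replicate 3, histones (−0.00167) without shPTX3 replicate 1 and FGF ligands and receptors (0.0192) without shPTX3 replicate 2. The FGF ligand and receptor median was also 0.0375 with replicates 2 and 3 alone and 0.0386 with the batch term and without shNT replicate 2, where hedgehog was 0.0136. With the replicate number as a block (replicate block), limma called 0 genes and camera 7 lists, the interferon list among them (adjusted p = 0.0236, but 0 lists with an estimated correlation), and PTX3 was −2.11 (adjusted p = 0.998). Deviations from the group means correlated across genes at 0.32, 0.07 and 0.06 for numbers 1, 2 and 3, shNT replicate 2 correlated best with shPTX3 replicate 3 (0.16), and the numbers were not treated as pairs. The authors' own comparison was not set beside the fit, since its column held 1 throughout. Genes near background, such as SLC25A31, are limited by signal.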

Other observations

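The tests and genes in this part were chosen after the results were seen, except the counts over other splits of the arrays.

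With replicate 1 as a batch term, the protein-coding genes with the smallest p after PTX3 included several that the comparison without it did not name, and none passed (limma adjusted p = 0.998 each). KCTD16, which encodes an auxiliary subunit of GABA-B receptors, differed by −1.86 (SE 0.30), with 5.79, 9.52 and 9.07 on the shNT arrays and 4.51, 6.75 and 7.54 on the shPTX3 arrays of replicates 1, 2 and 3. The cAMP phosphodiesterase PDE7B differed by −1.34 (SE 0.27), the interferon-inducible chemokine CXCL11 by −1.27 (SE 0.28), the prostaglandin transporter SLCO2A1 by −1.10 (SE 0.24) and the junction protein plakoglobin, JUP, by −0.87 (SE 0.21). The organic anion transporter SLCO4C1 was higher by 0.87 (SE 0.20). CXCL11 read 4.88, 5.69 and 6.46 on the shNT arrays and 3.60, 4.46 and 5.16 on the shPTX3 arrays. These values lay mostly below the array medians of the tested genes (5.68 to 5.76), so its difference may be limited by signal.

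Both replicate 1 arrays stood apart from the other 4, along a component with 33.4% of the variance. One stray array is argued against by the 161 genes detected on all 6 arrays and at least 4-fold apart in shNT. Of these, 100% differed in the same direction in shPTX3 (median 2.37 for the 58 higher and −2.16 for the 103 lower ones). Direction alone is a weak test, since the same pick from shNT replicate 2 or 3 gave 80% to 93.3% in shPTX3 replicates 2 and 3. Lower detection on the replicate 1 arrays is argued against by the 47055 genes detected on all 6 arrays. On their first component the replicate 1 arrays lay 2.055 times as far from the nearest other array as the range of the other 4. A different state of the replicate 1 cultures, such as density, medium or an ongoing interferon response, may account for it, and so could a separate labelling batch. No record of either was used here, so they cannot be told apart.

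The 5 shifted lists rest on the preset correlation: 0 of the 5 were called with an estimated correlation, which is consistent with members that vary together between cultures. With replicate 1 as a batch term and without shNT replicate 2, 2 of the 5 lists still passed with the preset correlation. These were FGF and ERK feedback (median −0.30, camera adjusted p = 0.00822) and cholesterol (0.21, 0.00822). Neither passed without the batch term (camera adjusted p = 0.0817 and 0.214) or with an estimated correlation. The FGF and ERK feedback mean was 0.151 on shNT replicate 2, against 0.113 and 0.15 on shNT replicates 1 and 3. These means argue against shNT replicate 2 alone carrying that list's mean, and its lowest array was shPTX3 replicate 2 (−0.384). For cholesterol the part of shNT replicate 2 stays open (−0.252, against 0.146 and −0.206 on shNT replicates 1 and 3). With the batch term and without shNT replicate 2, NF-kB and histones did not pass. Their medians moved from −0.25 and 0.15 to −0.13 and 0.02, so shNT replicate 2 may account for part of both shifts. Oxidative phosphorylation did not pass there either (adjusted p = 0.142), but its median stayed near its size (0.12 against 0.14), so the part of shNT replicate 2 in it stays open, as does the silencing of PTX3 for all 5 lists. Among the 10 splits of the 6 arrays, 5 gave at least 5 lists: the real one and the 4 that keep both replicate 1 arrays on one side. The highest other gave 13, and the remaining splits gave between 0 and 4 lists. A share under 0.05 cannot be reached with 10 splits.

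No gene passed the threshold although PTX3 had the smallest p. Spread from the replicate 1 difference may hide changes, though 0 genes passed with it as a batch term. Genes at an unadjusted p under 0.05 went from 2632 to 3557, still below the 3791 that chance alone gives. Replicates 2 and 3 alone gave 4017, above that number. Over the 18170 protein-coding genes fitted alone, the count went from 405 to 961 with the batch term. The fit in which PTX3 passed had 907 of 16178 genes. Both 961 and 907 are slightly above a share of 0.05. In the simulation with the spread within groups, 6%, 62%, 84% and 94% of 2-fold, 4-fold, 8-fold and 16-fold changes were recovered. A simulation with the spread left after the replicate 1 difference is removed gave 10%, 74%, 86% and 92%, with 3 false calls instead of 2. Both were fitted without the batch term and drew their own changed genes, so the gain from that term was not measured. Whether that spread hides changes stays open, and changes too small for 3 arrays a group may be present. The real split called 0 genes, so that all 10 splits necessarily gave at least as many (highest other 0), and the count decides nothing. Unadjusted p-values under 0.05 numbered 5154 to 6179 in the 4 splits that keep both replicate 1 arrays together and 2373 to 3257 in the other 6, the real split included, which points to that structure of the arrays.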
